A study of Mus musculus with 32 samples.

How the data were processed

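The samples were Acly knockout mouse embryonic fibroblasts that carried mCherry alone (KO) or mCherry fused to human ACLY (WT), to ACLY with a nuclear export sequence (Cyto) or to ACLY with added nuclear import sequences (Nuc). They were cultured for 24 h in DMEM with 10% calf serum and either 10 mM or 1 mM glucose. The series has 32 libraries, 4 per construct and medium, of which 15 in 10 mM glucose and 16 in 1 mM glucose were analysed. Per the labels, RNA was extracted with Qiagen RNeasy Plus kits, and libraries were made and sequenced by Novogene. The labels do not say whether libraries of a group came from separate cultures, or whether a construct was introduced into cells more than once. The p-values therefore measure the spread among these samples, which may be technical, and not among independently made cell lines.

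The authors deposited 1 table per medium with gene-level values in log2, which fit log2 CPM (counts scaled to a common library size) with a small offset and a scaling factor between libraries. Per the labels, reads were assigned with kallisto on GRCm39 and processed with edgeR and limma. Versions, settings and the minimum that a gene had to pass to be listed are not stated. The tables were normalized separately, and every library of a table has the same lowest value, -3.293 in 10 mM and -3.592 in 1 mM glucose. Whole read counts could not be recovered from the values, so the depth of each library is unknown, no counting intervals are given, and a gene at the lowest value is not shown to be absent. The entry without a gene symbol, 1 in each table, was left out of all tests. That left 12791 genes in 10 mM and 12053 in 1 mM glucose, 11931 of them in both. No value was filtered or transformed further for the reported results.

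Differences between constructs were tested within each table with limma 3.58.1 in R 4.3.3. All 4 constructs were in 1 fit of group means with an intensity trend in the prior variance, and genes with a Benjamini-Hochberg adjusted p under 0.05 over the table were called. The 6 comparisons per medium were WT, Cyto and Nuc against KO, Nuc against Cyto, and Cyto and Nuc against WT. Whether 4 of these fold changes differed between media was tested by limma on the shared genes, as the log2 fold change in 1 mM minus that in 10 mM glucose. Each medium was sequenced in its own batch, so levels were not compared between media, and a difference of fold changes removes only batch effects that are equal in all constructs.

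Of 34 gene lists written from general knowledge, 32 had at least 5 measured members in 10 mM and 31 in 1 mM glucose. They were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list with the other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it, camera was run with a correlation estimated from the residuals, and fry, which asks whether a list's genes moved on balance in 1 direction. The fit and the tests were checked on simulated data. For the fit, 200 genes were changed per comparison, with independent normal noise around each gene's mean. The real comparisons called many more genes, so the rates below hold for that setting only. Of genes changed by 0.5, 1 and 2 on the log2 scale between Nuc and Cyto, 40.3%, 79.1% and 95.5% were called in 10 mM glucose and 61.2%, 88.1% and 98.5% in 1 mM glucose. For the difference between media 31.3%, 65.7% and 95.5% were called. Calls of unchanged genes made up 5.30%, 5.71% and 3.76% of all calls.

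Genes were named by a rule. Acly came first. For the comparisons with KO and of Nuc with Cyto the rule took the 5 highest and the 5 lowest log2 fold changes among called genes. These had a mean at or above that of the median gene of the table and groups that did not overlap, and symbols of Gm plus digits, ending in Rik or repeating an identifier were passed over. Up to 4 members per list with the smallest adjusted p were added. For the comparisons with WT it took 2 at each end and up to 2 per list, and for differences between media 4 at each end, with overlap allowed, and up to 2 per list. Some genes of the rule are left out of the text, and genes named for 1 comparison also have values in others. Naalad2, Fbn2, Gpm6b, Pax2, Rhox5, Sgce, Peg10, Mef2c, Tgfbi and the levels of C3 per library were chosen after their values were seen. Some genes are not reported here.

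Alternatives were a prior variance without trend, equal library medians, quantile normalization within a table, 1 added on the linear scale, a minimum mean log2 value of 0, limma's arrayWeights, the replicate number as a term, a fit of the 2 groups alone, and leaving out each library in turn. The comparisons, tests, gene lists, rule and these alternatives were chosen before the data were examined. Removing each library's trend on transcript length, as a spline with 5 degrees of freedom, and leaving out all libraries numbered 4 in 10 mM glucose were added after seeing the data. Transcript lengths came from a GRCm38 annotation, matched by symbol for 97.6% of genes, and no genome coordinates are given because that build differs from the one of the tables. Shares of mitochondrially encoded transcripts were compared by exact permutation tests, two-sided. All shares are of the total that CPM is scaled to, called the nominal CPM total here. Each library's own sum of values ran from 0.933 to 1.10 times that total.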

Results

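RNA was sequenced from mouse embryonic fibroblasts with a knockout of the endogenous Acly gene, which encodes ATP-citrate lyase (ACLY), the enzyme that splits citrate into acetyl-CoA and oxaloacetate outside mitochondria. The cells carried 1 of 4 constructs. KO cells expressed the red fluorescent protein mCherry alone. The others expressed human ACLY fused to mCherry, either unmodified (WT), with a nuclear export sequence (Cyto) or with added nuclear import sequences (Nuc). Each line was cultured for 24 h in 10 mM or in 1 mM glucose, with 4 libraries per construct and medium in the labels. In 10 mM glucose 15 libraries were analysed (3 of Cyto, 4 of every other construct) and in 1 mM glucose 16. The Cyto library numbered 3 in 10 mM glucose, which the submitters described as an anomaly, was not analysed here. Values covered 12791 genes in 10 mM and 12053 genes in 1 mM glucose. The depth of the libraries is unknown, because the tables hold log2 CPM (counts scaled to a common library size) values rather than read counts. The first principal component held 28.1% of the variance in 10 mM and 39.1% in 1 mM glucose. Mitochondrially encoded transcripts made up 4.74% ± 0.0391 (SD, n = 4) of the nominal CPM total in KO and 3.51% ± 0.026 in WT libraries. Both values are for 10 mM glucose. These shares in 1 mM glucose were 1.76% ± 0.138 and 1.25% ± 0.0484. All libraries in 10 mM glucose were sequenced in batch 2 and all in 1 mM glucose in batch 1, so levels set across the media also cross batches and separate normalizations. Below, ± after a log2 fold change is limma's standard error, with n = 4 libraries per group except n = 3 for Cyto in 10 mM glucose.

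Acly itself was examined first, as a check of the labels. In 10 mM glucose its mean log2 level was 5.87 ± 0.21 (SD) in KO, 10.21 ± 0.06 in WT, 9.74 ± 0.13 in Cyto and 9.12 ± 0.12 in Nuc. In 1 mM glucose the levels were 5.35 ± 0.10, 10.57 ± 0.10, 10.50 ± 0.07 and 8.97 ± 0.08. Every library with an ACLY construct lay above every KO library. KO libraries still held transcript assigned to Acly, far above the lowest values of -3.293 in 10 mM and -3.592 in 1 mM glucose. Against KO, Acly was 20.3-fold, 14.6-fold and 9.49-fold higher in WT, Cyto and Nuc in 10 mM glucose, and 37.3-fold, 35.7-fold and 12.3-fold higher in 1 mM glucose. The constructs also differed from each other. Nuc cells had less Acly transcript than Cyto cells, with log2 fold changes of -0.62 ± 0.10 and -1.53 ± 0.07 in 10 mM and 1 mM glucose. Cyto was lower than WT in 10 mM glucose (-0.47 ± 0.10, limma adjusted p = 0.00157), a call that was lost with quantile normalization (-0.31, adjusted p = 0.0555). In 1 mM glucose Cyto and WT differed by -0.06 ± 0.07 (adjusted p = 0.425). That difference became 0.27 (adjusted p = 0.0214) with quantile normalization and -0.15 (adjusted p = 0.0482) once each library's trend on transcript length was removed, so its direction depended on the scaling. The transgene is human and the tables list mouse genes, and how its reads were assigned is not given in the sources used here.

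**Figure D1:**
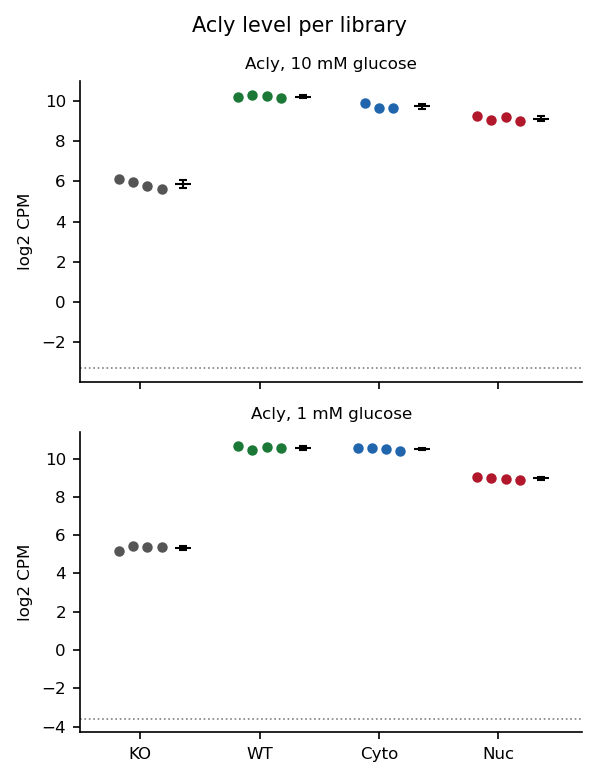
Level of Acly in log2 CPM per library for the 4 constructs in 10 mM glucose (top) and 1 mM glucose (bottom). Points are libraries, black marks are means with SD, and the dotted line is the lowest value of the table. Acly lay at 5.87 and 5.35 in KO and at 8.97 or more in the other constructs.

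The first question was what ACLY without a localization signal changed in 10 mM glucose. Genes of cholesterol synthesis were lower in WT than in KO cells. Nsdhl and Sc5d, which encode enzymes of late sterol synthesis, had log2 fold changes of -1.57 ± 0.07 and -1.74 ± 0.10. Acat2, whose product joins 2 acetyl-CoA molecules at the entry to the pathway, had -1.32 ± 0.08, and Idi1 had -1.16 ± 0.07. Of 24 measured sterol genes 19 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.80 (camera adjusted p = 2.88e-09, and 0.035 with an estimated correlation). Fatty acid synthesis genes fell in part, 12 of 20 against 2 that rose, the same counts adjusted over the list alone (median -0.40, adjusted p = 7.92e-04, and 0.035 with an estimated correlation). Among these were Acsl3 (-1.16 ± 0.09), an acyl-CoA synthetase, Scd1 (-0.65 ± 0.07), a desaturase, and Fasn (-0.58 ± 0.07), the fatty acid synthase. Abca1, a cholesterol exporter, rose by 1.46 ± 0.16.

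Cell cycle genes were also lower in WT than in KO, among them Cdc6 (-1.38 ± 0.10), which licenses replication origins, the helicase subunit Mcm6 (-0.81 ± 0.06), the topoisomerase Top2a (-0.85 ± 0.05) and Uhrf1 (-0.84 ± 0.06), which maintains DNA methylation. Of 40 measured members 32 fell and 0 rose (33 and 0 adjusted over the list alone; median -0.48, camera adjusted p = 1.02e-12, and 0.00868 with an estimated correlation). Matrix genes were higher. The gelatinase Mmp2 rose by 1.67 ± 0.05, Fbln5 of elastic fibres by 1.61 ± 0.05, Postn by 1.54 ± 0.05 and the collagen gene Col5a1 by 1.04 ± 0.04. Of 38 matrix genes 27 rose and 5 fell (29 and 6 adjusted over the list alone; median 0.62, adjusted p = 1.07e-11, and 0.00868 with an estimated correlation). Hypoxia response genes rose as well, 12 of 18 against 1 that fell, with the same counts adjusted over the list alone. P4ha1, a collagen prolyl hydroxylase, had 1.06 ± 0.07 and Ero1a, an oxidase of the endoplasmic reticulum (ER), 1.03 ± 0.08 (list median 0.51, adjusted p = 3.99e-05, and 0.00868 with an estimated correlation). Secreted inflammatory factors fell in 10 of 16 cases and rose in 3, as they did adjusted over the list alone. The chemokine genes Ccl2 and Ccl7 had -3.02 ± 0.12 and -2.25 ± 0.12, and Ptgs2, an inducible cyclooxygenase, -1.41 ± 0.09 (list adjusted p = 0.00859, and 0.172 with an estimated correlation).

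Outside the lists, Clu, an extracellular chaperone, and Emb, a cell adhesion protein, were among the highest at 2.08 ± 0.12 and 2.04 ± 0.08, and Slc1a3, a glutamate transporter, and Serpina3g, a protease inhibitor, among the lowest at -2.83 ± 0.13 and -2.47 ± 0.12. In all, limma called 5218 of 12791 genes, 2631 higher and 2587 lower in WT, and 926 of these changed at least 2-fold. The adjusted p of the genes named for this comparison was at most 1.08e-05.

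The export construct was compared with KO next. Where ACLY lay in the cells was not measured in these data. In Cyto cells in 10 mM glucose, the sterol genes went both ways. Sc5d (-1.32 ± 0.11) and Stard4 (-0.86 ± 0.08), a cholesterol transport protein, fell, whereas Insig1, a sterol sensor of the ER, rose by 2.18 ± 0.09. The list did not pass (11 of 24 fell, 3 rose, 11 and 3 adjusted over the list alone; median -0.32, camera adjusted p = 0.0833). Abca1 rose by 3.00 ± 0.18, and Npc1, which moves cholesterol out of lysosomes, rose by 0.67 ± 0.09. The list of LXR targets and cholesterol efflux had 7 of 13 genes up and 1 down, also adjusted over the list alone (median 0.47, adjusted p = 0.00637, and 0.0567 with an estimated correlation). Glycolysis genes rose in 13 of 24 cases and fell in 0 (14 and 0 adjusted over the list alone; median 0.32, adjusted p = 1.42e-04, and 0.164 with an estimated correlation). Aldolase Aldoa had 1.08 ± 0.08, the phosphofructokinase genes Pfkp and Pfkl 1.01 ± 0.08 and 0.92 ± 0.07, and the glucose transporter Slc2a1 0.80 ± 0.08.

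Cyto cells also had lower cell cycle genes than KO cells, 34 of 40 with 0 higher (35 and 0 adjusted over the list alone; median -0.66, camera adjusted p = 3.71e-17, and 0.00447 with an estimated correlation). Mcm5 had -1.46 ± 0.08, Top2a -1.09 ± 0.05 and Uhrf1 -1.10 ± 0.06. Hypoxia genes, with the growth factor Vegfa at 1.10 ± 0.10 and P4ha1 at 1.03 ± 0.07, rose in 12 of 18 cases (13 adjusted over the list alone; median 0.69, adjusted p = 2.65e-06, and 0.00447 with an estimated correlation). Matrix genes rose in 22 of 38 cases and fell in 6 (23 and 6 adjusted over the list alone), with Fbln5 at 1.44 ± 0.06 and the membrane protease Mmp14 at 1.10 ± 0.06 (median 0.38, adjusted p = 8.48e-06, and 0.0363 with an estimated correlation). Loxl2, a lysyl oxidase, and Pde3b, a phosphodiesterase, were 2.54 ± 0.15 and 2.49 ± 0.19 higher. Sorl1, a sorting receptor, Adamts9, a matrix protease, and Lama4, a laminin chain, were among the lowest at -2.29 ± 0.24, -2.11 ± 0.10 and -2.03 ± 0.09. The antigen processing genes Psmb9 and Tap1 had -1.96 ± 0.21 and -1.29 ± 0.15. Ankrd1, a target of the YAP coactivator, stood at a mean log2 level of 4.62 in Cyto against 0.13 in KO. limma called 4927 genes, 2504 higher and 2423 lower, and 1032 changed at least 2-fold. For the named genes the adjusted p was at most 3.18e-04.

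In Nuc cells, which carried ACLY with added nuclear import sequences, sterol genes were lower than in KO again. Of 24 members 20 fell and 2 rose, also adjusted over the list alone (median -0.79, camera adjusted p = 3.37e-08, and 0.064 with an estimated correlation). Sc5d had -1.43 ± 0.10, Nsdhl -1.37 ± 0.07 and Acat2 -1.16 ± 0.08. Matrix genes had their highest median of the comparisons against KO in this medium, 0.79, with 30 of 38 up and 3 down (31 and 3 adjusted over the list alone; adjusted p = 1.14e-14, and 0.00502 with an estimated correlation). Loxl2 rose by 3.01 ± 0.14, Mmp2 by 1.84 ± 0.05, Fbln5 by 1.54 ± 0.05 and Col11a1 by 1.54 ± 0.06. Itga11, a collagen receptor, and Tagln, an actin-binding protein of contractile cells, rose by 2.83 ± 0.10 and 2.37 ± 0.13.

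Genes that respond quickly to growth factors fell in Nuc, 16 of 24 against 6 that rose (17 and 6 adjusted over the list alone; median -0.55, camera adjusted p = 0.00314, and 0.28 with an estimated correlation). Fos had -3.19 ± 0.16, Egr1 -1.30 ± 0.08 and the phosphatase Dusp1 -1.70 ± 0.12. Secreted factors fell too, with Cxcl1 at -3.36 ± 0.17, Ccl2 at -2.59 ± 0.12 and Ptgs2 at -2.17 ± 0.09 (9 of 16 lower and 3 higher, also adjusted over the list alone; adjusted p = 0.0261, and 0.28 with an estimated correlation). Of 40 cell cycle genes 33 fell and 0 rose (34 and 0 adjusted over the list alone; median -0.51, adjusted p = 1.27e-11, and 0.0164 with an estimated correlation), with Mcm5 at -1.49 ± 0.07, Uhrf1 at -1.27 ± 0.06 and Mcm4 at -1.05 ± 0.05. Hk2, a hexokinase, rose by 1.51 ± 0.09 and Has2, which makes hyaluronan, by 1.02 ± 0.09. G6pdx, of the pentose phosphate pathway, and the acetyl-CoA synthetase Acss2 fell by 1.32 ± 0.10 and 1.02 ± 0.15. Ces2g, a carboxylesterase, was the lowest gene of the rule at -3.46 ± 0.09. The total was 5800 genes, 2898 higher and 2902 lower, with 1163 changed at least 2-fold. Named genes had adjusted p of at most 2.95e-05.

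Nuc was then compared directly with Cyto. These groups also differ in Acly transcript and may differ as cell lines, so an effect of the place of ACLY cannot be isolated. In 10 mM glucose, sterol genes were lower in Nuc, with 16 of 24 down and 0 up (16 and 2 adjusted over the list alone; median -0.41, camera adjusted p = 1.15e-06, and 0.108 with an estimated correlation). Insig1 had -1.46 ± 0.09, Fdft1, the squalene synthase, -1.30 ± 0.09 and Nsdhl -0.93 ± 0.07. Matrix genes were higher in Nuc, 24 of 38 against 4 (25 and 4 adjusted over the list alone; median 0.37, adjusted p = 5.09e-07, and 0.0361 with an estimated correlation), among them Mmp2 (1.69 ± 0.05) and the collagen genes Col6a2 (1.23 ± 0.05) and Col6a1 (1.02 ± 0.05). Adamts9 and Svep1, an adhesion protein of the matrix, were among the highest at 3.02 ± 0.10 and 2.31 ± 0.15. The contractile genes Tagln and Myl9 rose by 1.85 ± 0.14 and 1.5 ± 0.11, while Ankrd1 stood at -1.95 in Nuc against 4.62 in Cyto. Secreted inflammatory factors were lower, 9 of 16 with 0 higher (11 and 0 adjusted over the list alone; median -0.64, adjusted p = 1.97e-06, and 0.0361 with an estimated correlation), including Ccl2 (-2.51 ± 0.13), Cxcl1 (-2.29 ± 0.19) and Ptgs2 (-1.82 ± 0.09).

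Early response genes were lower in Nuc than in Cyto as well, 16 of 24 against 2 (18 and 2 adjusted over the list alone; median -0.50, camera adjusted p = 4.8e-06, and 0.183 with an estimated correlation), with Dusp1 at -1.20 ± 0.13, Egr1 at -1.11 ± 0.09 and Myc at -0.80 ± 0.08. Glycolysis genes fell in 13 of 24 cases and rose in 4, as they did adjusted over the list alone (median -0.24, adjusted p = 0.0118, and 0.481 with an estimated correlation). Pgk1 had -0.94 ± 0.08 and Pfkp -0.84 ± 0.08. Psmb9 and Tap1 were 2.02 ± 0.21 and 1.31 ± 0.15 higher, and Tubb3, a tubulin typical of neurons, 3.50 ± 0.20 higher. The cell cycle list did not pass (15 of 40 higher and 7 lower, 16 and 8 adjusted over the list alone; median 0.15, adjusted p = 0.145). Foxm1 and Rrm2 rose by 0.87 ± 0.09 and 0.64 ± 0.06 and Mcm6 fell by 0.63 ± 0.06. limma called 3963 genes, 1961 higher and 2002 lower in Nuc, 780 of them at least 2-fold, and the named genes had adjusted p of at most 1.42e-04. The fatty acid synthesis list (7 of 20 lower and 1 higher, 8 and 1 adjusted over the list alone; adjusted p = 0.0425, and 0.183 with an estimated correlation) lost its call without the libraries numbered 4 (adjusted p = 0.0979) and with length trends removed (adjusted p = 0.0539).

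Against WT in 10 mM glucose, Cyto cells had higher sterol genes, 19 of 24 with 0 lower, also adjusted over the list alone (median 0.47, camera adjusted p = 4.35e-09, and 0.0538 with an estimated correlation), including Insig1 (1.26 ± 0.09) and Nsdhl (1.14 ± 0.07). Ccl2 and Ccl7 were 2.93 ± 0.13 and 1.62 ± 0.12 higher, within a list of secreted factors with 10 of 16 up and 0 down, also adjusted over the list alone (adjusted p = 7.52e-07, and 0.0538 with an estimated correlation). Fasn rose by 0.81 ± 0.08 and Abca1 by 1.55 ± 0.18. Mmp2 (-1.52 ± 0.05) and Col6a2 (-1.04 ± 0.05) were lower than in WT. Nuc cells had Tagln 3.57 ± 0.13 and Ctsk, a collagen-degrading protease, 2.81 ± 0.09 above WT. In Nuc the proteoglycan Dcn was 1.86 ± 0.14 higher and Has2 1.68 ± 0.09 higher, and Fos (-2.76 ± 0.16), Ces2g (-2.83 ± 0.09) and Clu (-2.58 ± 0.12) were lower. The matrix and early response lists of Nuc against WT had camera adjusted p = 0.0285 each, and 0.568 and 0.801 with an estimated correlation. Removing length trends ended both calls (adjusted p = 0.0919 and 0.0687). limma called 4033 genes for Cyto against WT (2040 higher, 1993 lower) and 3685 for Nuc against WT (1922 higher, 1763 lower).

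In 1 mM glucose, genes of protein folding in the ER were higher in WT than in KO. Sdf2l1 and Creld2, both chaperone-associated proteins of the ER stress response, rose by 3.58 ± 0.18 and 3.17 ± 0.18, Manf by 2.35 ± 0.14, the chaperone Hyou1 by 1.85 ± 0.09 and the ubiquitin ligase Syvn1 by 1.60 ± 0.06. Of 21 members 20 rose and 0 fell, also adjusted over the list alone (median 1.54, camera adjusted p = 1.55e-12, and 0.229 with an estimated correlation). Sterol genes fell in 23 of 24 cases and rose in 1, with the same counts adjusted over the list alone (median -1.99, adjusted p = 2.75e-15, and 0.229 with an estimated correlation). Nsdhl had -3.23 ± 0.12, Acat2 -3.07 ± 0.13, Sc5d -2.62 ± 0.09 and Idi1 -2.57 ± 0.09. Acss2 fell by 3.03 ± 0.14, the cytosolic isocitrate dehydrogenase Idh1 by 1.60 ± 0.08, Acsl3 by 1.62 ± 0.06 and the desaturases Fads2 and Fads1 by 1.20 ± 0.06 and 1.06 ± 0.05. The fatty acid synthesis list had 15 of 20 down and 2 up, also adjusted over the list alone (median -0.82, adjusted p = 2.79e-05, and 0.229 with an estimated correlation). Abca1 rose by 2.75 ± 0.15.

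ATF4 and amino acid response genes rose in 23 of 26 cases in WT and fell in 1 (24 and 1 adjusted over the list alone; median 0.41, camera adjusted p = 1.77e-05, and 0.323 with an estimated correlation). The stress factors Ddit3 and Ppp1r15a had 2.09 ± 0.18 and 1.98 ± 0.19. Slc2a3, a high-affinity glucose transporter, was 3.62 ± 0.15 higher and Hk2 1.24 ± 0.08 higher. Cell cycle genes fell in 28 of 39 cases and rose in 2, also adjusted over the list alone (median -0.51, adjusted p = 3.76e-06, and 0.37 with an estimated correlation), with Mki67 at -1.04 ± 0.12, Ccnb1 at -1.03 ± 0.12 and Top2a at -0.91 ± 0.10. Cdkn1a, an inhibitor of cyclin-dependent kinases, rose by 1.23 ± 0.05. Matrix genes rose in 26 of 38 cases and fell in 6 (27 and 6 adjusted over the list alone; median 0.36, adjusted p = 1.32e-04, and 0.49 with an estimated correlation), with Mmp2 at 1.58 ± 0.06 and Fbln5 at 1.31 ± 0.06, while Dcn fell by 1.97 ± 0.09. Gpr141, an orphan receptor, and Rspo2, a Wnt pathway ligand, were among the lowest at -3.49 ± 0.12 and -2.57 ± 0.07. limma called 7014 of 12053 genes, 3580 higher and 3434 lower, with 1292 changed at least 2-fold. Named genes had adjusted p of at most 1.73e-06.

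Cyto against KO gave the most calls of any comparison. ER folding genes rose in 21 of 21 cases, also adjusted over the list alone (median 2.24, camera adjusted p = 9.15e-14, and 0.208 with an estimated correlation). Sdf2l1 rose by 4.77 ± 0.18, Creld2 by 4.26 ± 0.18, the main ER chaperone Hspa5 by 3.34 ± 0.13 and Hyou1 by 3.28 ± 0.09. ATF4 targets rose in 22 of 26 cases and fell in 2, also adjusted over the list alone (median 1.04, adjusted p = 1.02e-07, and 0.208 with an estimated correlation). Ppp1r15a had 3.34 ± 0.19, the cystine transporter Slc7a11 3.07 ± 0.13 and the amino acid transporter Slc7a5 1.03 ± 0.05. Antioxidant genes of the NRF2 list rose in 12 of 19 cases and fell in 4, also adjusted over the list alone (median 0.31, adjusted p = 0.0466, and 0.27 with an estimated correlation). Hmox1, a heme oxygenase, had 3.12 ± 0.10, Gclc of glutathione synthesis 1.69 ± 0.07 and the thioredoxin reductase Txnrd1 1.29 ± 0.06. Interferon response genes rose in 21 of 29 cases and fell in 5, also adjusted over the list alone (median 1.11, adjusted p = 4.18e-04, and 0.248 with an estimated correlation), among them Usp18 (2.95 ± 0.21), Xaf1 (2.12 ± 0.10) and Irf9 (1.13 ± 0.07).

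Cell cycle genes of Cyto cells were lower than in KO in 37 of 39 cases, also adjusted over the list alone, and higher in 0 (median -1.13, camera adjusted p = 5.51e-12, and 0.208 with an estimated correlation), with Mki67 at -2.08 ± 0.12, Mcm5 at -1.68 ± 0.07 and Uhrf1 at -1.56 ± 0.10. Sterol genes fell in 19 of 24 cases and rose in 2, also adjusted over the list alone (median -1.17, adjusted p = 2.08e-06, and 0.333 with an estimated correlation), with Acat2 at -2.95 ± 0.13, Dhcr7 at -2.54 ± 0.12 and Sc5d at -1.72 ± 0.09. Fasn, Fads2 and Scd1 fell by 1.43 ± 0.09, 1.42 ± 0.06 and 1.57 ± 0.10. Matrix genes went both ways and the list did not pass (20 of 38 fell and 12 rose, also adjusted over the list alone; median -0.25, adjusted p = 0.395). Col8a1 (-1.63 ± 0.11) and Col3a1 (-1.08 ± 0.08) fell, whereas Postn rose by 1.18 ± 0.07. The homeobox gene Prrx2 (-2.58 ± 0.12), Mgp (-2.52 ± 0.13) and Cd248 (-2.47 ± 0.13) were among the lowest. Ptgs2, the stress factor Atf3 and Spry4, a feedback inhibitor of growth factor signalling, rose by 3.40 ± 0.25, 3.32 ± 0.14 and 2.86 ± 0.18. Abca1 rose by 3.31 ± 0.15 and Hk2 by 1.80 ± 0.08, and Ankrd1 stood at 3.65 against -1.98 in KO. limma called 7802 genes, 3821 higher and 3981 lower, with 1997 changed at least 2-fold. Adjusted p of the named genes was at most 4.37e-09.

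Nuc cells were compared with KO in 1 mM glucose next. ER folding genes rose in 20 of 21 cases and fell in 0, also adjusted over the list alone (median 2.30, camera adjusted p = 2.74e-15, and 0.306 with an estimated correlation), with Sdf2l1 at 4.65 ± 0.18, Creld2 at 4.45 ± 0.18, Hyou1 at 3.17 ± 0.09, Syvn1 at 2.34 ± 0.06 and Edem1, which directs misfolded proteins to degradation, at 2.07 ± 0.07. All 24 measured sterol genes fell, also adjusted over the list alone (median -1.61, adjusted p = 3e-14, and 0.306 with an estimated correlation), including Acat2 (-2.89 ± 0.13), Nsdhl (-2.70 ± 0.12), Dhcr7 (-2.68 ± 0.12) and Idi1 (-2.14 ± 0.09). Acss2 fell by 2.35 ± 0.14 and Idh1 by 1.54 ± 0.08. ATF4 genes rose in 22 of 26 cases and fell in 2, also adjusted over the list alone (median 0.74, adjusted p = 1.17e-06, and 0.345 with an estimated correlation), with Ddit3 at 2.72 ± 0.18 and Slc7a11 at 2.33 ± 0.13. Slc2a3 and Hk2 rose by 4.29 ± 0.15 and 2.10 ± 0.08, while Txnip, which restrains glucose uptake, fell by 3.71 ± 0.25. Gfpt1, the first enzyme of hexosamine synthesis, and Gnpnat1 of the same pathway rose by 1.60 ± 0.10 and 1.59 ± 0.13.

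In the same comparison C3, a complement component, fell by 4.01 ± 0.11, Ces2g by 3.62 ± 0.09 and Serpina3g by 2.55 ± 0.08. Loxl2, Tagln and Col5a1 rose by 2.46 ± 0.14, 2.36 ± 0.15 and 0.98 ± 0.06, and Abca1 by 2.66 ± 0.15. Cell cycle genes fell in 29 of 39 cases and rose in 3 (29 and 4 adjusted over the list alone; median -0.44, camera adjusted p = 9.35e-05, and 0.542 with an estimated correlation), with Mcm6 at -1.29 ± 0.07 and Mcm4 at -1.25 ± 0.06. limma called 7232 genes, 3678 higher and 3554 lower, with 1476 changed at least 2-fold, and the named genes had adjusted p of at most 1.92e-08.

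Between Nuc and Cyto in 1 mM glucose, cell cycle genes were higher in Nuc, 30 of 39 against 2, also adjusted over the list alone (median 0.59, camera adjusted p = 8.51e-09, and 0.432 with an estimated correlation). Mki67 had 1.52 ± 0.12, the ribonucleotide reductase subunit Rrm2 1.36 ± 0.10 and the mitotic kinase Aurkb 1.27 ± 0.11. Matrix genes were higher in 30 of 38 cases and lower in 4, also adjusted over the list alone (median 0.50, adjusted p = 8.51e-09, and 0.432 with an estimated correlation), with Fbln2 at 1.26 ± 0.06, Mmp2 at 1.14 ± 0.06 and Col5a1 at 0.98 ± 0.06. NRF2 genes were lower in 15 of 19 cases and higher in 2, also adjusted over the list alone (median -0.50, adjusted p = 1.77e-06, and 0.0427 with an estimated correlation). Hmox1 had -1.69 ± 0.10 and the glutathione synthesis genes Gclm and Gclc -1.45 ± 0.10 and -0.89 ± 0.07. Interferon genes were lower in 18 of 29 cases and higher in 2 (20 and 3 adjusted over the list alone; median -0.57, adjusted p = 3.1e-05, and 0.373 with an estimated correlation), with Mx2 at -2.53 ± 0.29, Ifi44 at -1.59 ± 0.12 and Ifit3 at -1.13 ± 0.11.

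Sterol genes were lower in Nuc than in Cyto in 1 mM glucose too, 14 of 24 against 2, also adjusted over the list alone (median -0.41, camera adjusted p = 2.26e-04, and 0.466 with an estimated correlation). Insig1 had -1.66 ± 0.08, Fdps, the farnesyl diphosphate synthase, -0.89 ± 0.12 and Fdft1 -0.68 ± 0.09. Pltp, which transfers phospholipids, and Lpcat3, which remodels them, rose by 1.30 ± 0.07 and 1.07 ± 0.07. Tagln was 3.94 ± 0.15 higher, Mgp 2.55 ± 0.13 and Svep1 2.27 ± 0.18. C3 (-5.50 ± 0.11), Slc1a3 (-2.41 ± 0.09) and the matrix protease Mmp9 (-2.10 ± 0.08) were among the lowest. Atf3 and Jun fell by 1.49 ± 0.14 and 1.14 ± 0.12. limma called 4939 genes, 2463 higher and 2476 lower in Nuc, with 783 changed at least 2-fold and adjusted p of at most 1.12e-05 for the named genes.

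Against WT in 1 mM glucose, ER folding genes were higher in both localized constructs, 20 of 21 in Cyto (median 0.83, camera adjusted p = 1.57e-07, and 0.431 with an estimated correlation) and 21 of 21 in Nuc (median 0.81, adjusted p = 2.37e-11, and 0.41 with an estimated correlation), in each case also adjusted over the list alone. Hyou1 was 1.43 ± 0.09 and 1.31 ± 0.09 above WT. Sterol genes were higher than in WT in 21 of 24 cases in Cyto and lower in 0 (median 0.62, adjusted p = 1.4e-07, and 0.431 with an estimated correlation). In Nuc 13 were higher and 2 lower (median 0.34 but mean 0.06, adjusted p = 0.00802, and 0.822 with an estimated correlation). Both counts were the same adjusted over the list alone. Fry did not call the sterol list in Nuc (adjusted p = 0.217). Cyp51 of sterol demethylation rose by 1.15 ± 0.07 and 0.99 ± 0.07. Slc7a11 was 3.82 ± 0.13 higher in Cyto and 3.07 ± 0.13 higher in Nuc, and Gpr141 3.98 ± 0.12 and 4.29 ± 0.12. Cyto cells had Ifi44 2.80 ± 0.12 and Hmox1 2.56 ± 0.10 above WT and Mmp2 below it (-1.91 ± 0.06). Nuc cells had Tagln 3.50 ± 0.15, Dcn 2.17 ± 0.09 and Has2 1.60 ± 0.12 above WT, and C3 (-2.56 ± 0.11) and Mcm4 (-1.06 ± 0.06) below it. Limma called 6418 genes for Cyto against WT (3099 higher, 3319 lower) and 4718 for Nuc against WT (2375 higher, 2343 lower).

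**Figure D2:**
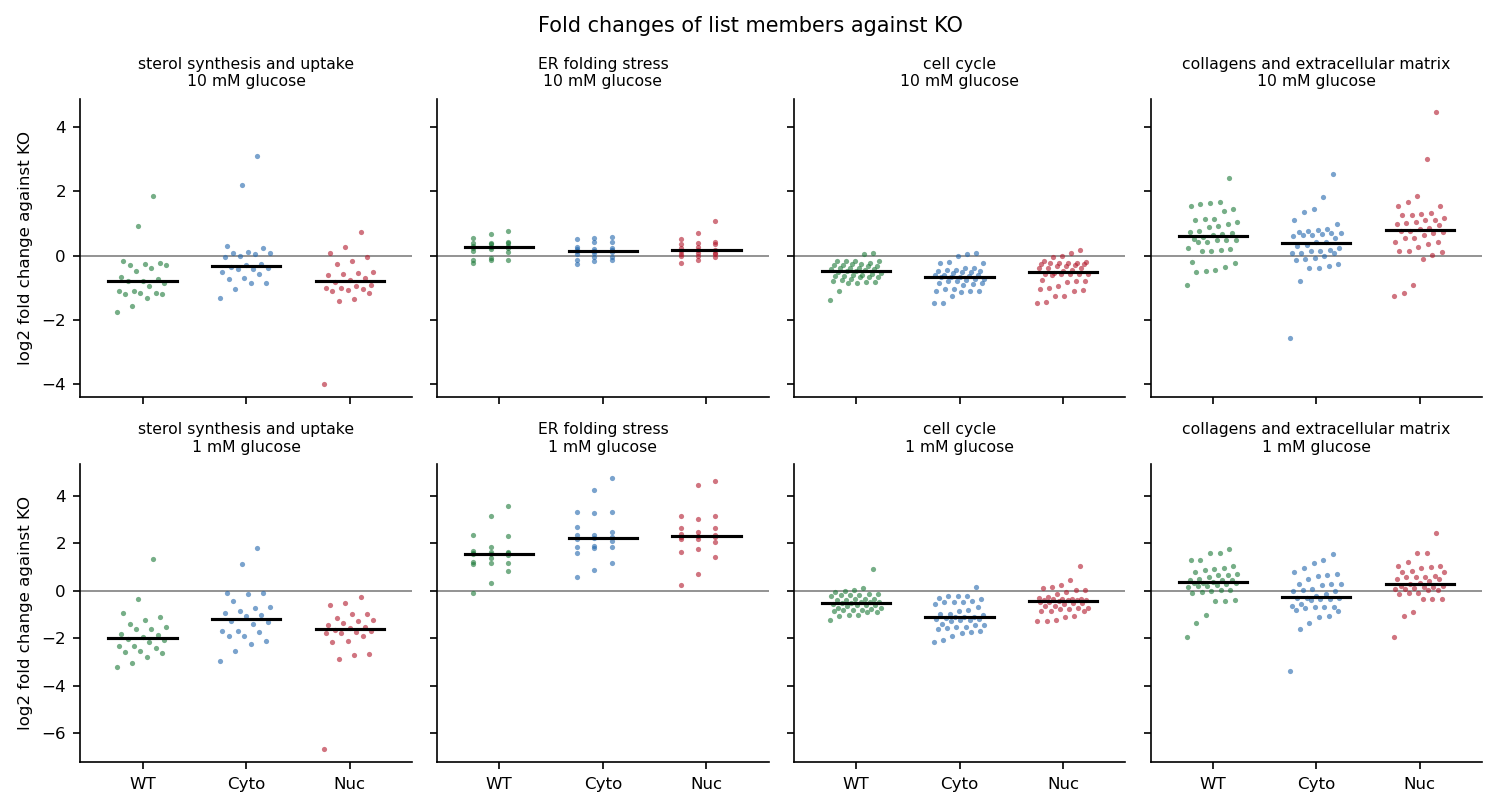
Log2 fold changes against KO of the measured members of 4 gene lists in WT, Cyto and Nuc cells, in 10 mM glucose (top) and 1 mM glucose (bottom). Each point is a gene and each black line the median of its list. The ER folding medians were 1.54, 2.24 and 2.30 in 1 mM glucose, and the cell cycle medians lay below 0 in all 6 comparisons.

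The fold changes of the 2 media were then compared with each other by limma on 11931 shared genes. The ER folding response to the constructs was larger in 1 mM glucose. Hyou1 differed by 1.98 ± 0.11 for WT against KO, 3.34 ± 0.11 for Cyto against KO and 3.13 ± 0.11 for Nuc against KO, and Sdf2l1 by 3.19 ± 0.25, 4.90 ± 0.26 and 4.77 ± 0.25. The list medians of these differences were 1.25, 2.23 and 2.18, with 19, 21 and 20 of 21 genes higher and 0 lower (camera adjusted p = 2.02e-24, 7.86e-23 and 7.47e-29, and 0.00742, 0.0161 and 0.00356 with an estimated correlation). Adjusted over the list alone, 20, 21 and 20 were higher. The list medians against KO in 1 mM glucose were 1.54, 2.24 and 2.30. For Cyto and Nuc the differences were thus nearly as large as the whole response in 1 mM glucose. Sterol genes fell further in 1 mM glucose, with medians of -1.08, -1.0 and -0.91 and with 23, 21 and 21 of 24 genes lower (24, 21 and 23 adjusted over the list alone). Their adjusted p was 2.77e-24, 1.47e-09 and 6.18e-13, and 0.00742, 0.114 and 0.0473 with an estimated correlation. Acat2 differed by -1.75 ± 0.16, -2.08 ± 0.17 and -1.74 ± 0.16. Txnip differed by -2.34 ± 0.26 in WT and -3.53 ± 0.26 in Nuc. For Cyto against KO, the interferon genes were higher by a median of 0.99 in 1 mM glucose (14 of 25 higher and 1 lower, also adjusted over the list alone; adjusted p = 6.61e-05, and 0.0472 with an estimated correlation), and Hmox1 differed by 3.51 ± 0.13. The difference between Nuc and Cyto itself depended on the medium for Tagln (2.09 ± 0.22), Hmox1 (-2.72 ± 0.13) and Adamts9 (-2.17 ± 0.17).

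In all, 3122 genes differed between media for WT against KO, 5332 for Cyto against KO, 4351 for Nuc against KO and 2261 for Nuc against Cyto. Most genes changed in both media went the same way: 3358 of 3677, 2810 of 3532, 3367 of 3981 and 2091 of 2324. Glucose and sequencing batch cannot be told apart in these differences.

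Genes that WT changed against KO were followed in the other constructs. Among the 5218 in 10 mM glucose, 2712 (52.0%) changed in the same direction in Cyto and 3351 (64.2%) in Nuc, and 2155 in both. Cyto had 3 libraries there and Nuc 4, so part of this gap can come from lower power in Cyto. In 1 mM glucose, of 7014 genes 4687 (66.8%) did so in Cyto and 4954 (70.6%) in Nuc, and 4014 in both. In the opposite direction 260 and 200 genes changed in 10 mM and 617 and 283 in 1 mM glucose. Independent lists of these sizes would share 1005 and 1183 genes in 10 mM and 2269 and 2105 in 1 mM glucose. With the KO libraries split into separate pairs, the mean overlaps were 1869 for Cyto and 2357 for Nuc in 10 mM, and 3757 and 3916 in 1 mM glucose. The covariance of the fold changes with those of WT was 0.24 for Cyto and 0.28 for Nuc in 10 mM glucose, against 0.03 in simulations of unchanged groups set against the same KO libraries, and 0.38 and 0.39 against 0.02 in 1 mM glucose. In correlation, across genes that are not independent replicates, the simulations with shared KO libraries and no change came nearer: 0.566 for Cyto and 0.603 for Nuc against 0.455 and 0.492 in 10 mM glucose, and 0.604 and 0.672 against 0.507 and 0.503 in 1 mM glucose. Of the 1196 genes that followed WT in Nuc and not in Cyto in 10 mM glucose, 793 differed between Nuc and Cyto, and of the 557 that followed WT in Cyto and not in Nuc, 338 did.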

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

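The tests of faster growth and of the sequencing batch were chosen only after the result was seen.

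Groups of 4 libraries for 8 genes and 3 shares of the libraries were searched for a library far from the others, 72 groups in all. The search found 3, and chance flags about 1 in 20 groups. In Nuc replicate 4 in 10 mM glucose Tgfbi was at 0.031, against a highest Nuc value of 1.63. C3 was at 6.56 in KO replicate 4 in 10 mM glucose, with the lowest KO library at 5.73. Naalad2 was at 3.58 in KO replicate 4 in 1 mM glucose, against a highest KO value of 3.92.

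The entry without a symbol, which no comparison used, had a higher value in every library of some constructs than in any KO library. Its values are shares of the nominal CPM total. In 10 mM glucose the shares were 0.0327% in WT, 0.0294% in Cyto and 0.0366% in Nuc, against 0.0275% in KO. Nuc in 1 mM glucose had 0.0144% against 0.0125% in KO. Cyto went the other way in 1 mM glucose, with 0.00931% and every library below every KO library. Each library's own sum was higher in the other constructs than in KO, which favours an excess. In 10 mM glucose the lowest Cyto library had 0.0286% and the highest KO library 0.0280%. Their sums were 1.0055 and 0.957 times the nominal total. Scaling can therefore account for the Cyto excess. The same holds for Nuc in 1 mM glucose (0.0140% and 0.0137%, sums 1.004 and 0.933). The WT and Nuc excess in 10 mM glucose was wider than the gap in sums. What the entry holds is not stated in the table.

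The libraries numbered 4 in 10 mM glucose and WT replicate 2 in 1 mM glucose were weighed as lying apart from their groups. By the SD over genes of log2 deviations from the group, these had 0.276 in WT, 0.273 in Cyto, 0.342 in Nuc and 0.307 in KO, where replicate 1 lay farther (0.361), and 0.386 in 1 mM glucose. A large shift in the growth state of these cultures is argued against by the cell cycle list, since its largest median deviation among the 5 libraries was 0.073. The deviation was above 0 in all 5 libraries and in each the highest of its group. A small shift is therefore not excluded. A library quality linked to transcript length may contribute: the deviation correlated with length across genes, which are not independent replicates, beyond a Spearman rho of 0.2 with the same sign in 4 of the 5 libraries, and in Cyto replicate 4 rho was only -0.15. Removing the length trend lowered the spread of WT replicate 2 from 0.386 to 0.350 and that of Nuc replicate 4 from 0.342 to 0.324, so most of the spread stayed unexplained, and no other biological explanation was tested.

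The effects of the constructs differed between media for 3122 genes in WT against KO, 5332 in Cyto against KO, 4351 in Nuc against KO and 2261 in Nuc against Cyto. Of 100 drawn splits of the libraries between media, only the real 1 gave as many, and the highest of the others gave 1130, 2310, 493 and 919. The other draws mix both media within a group, which raises the spread and favours the real split in advance. They therefore do not exclude chance for these counts, nor a batch effect that differs between constructs.

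For WT against KO, the lists with a higher response in 1 mM glucose were ATF4 targets (median difference 0.43), ER folding (1.25), early growth factor response (0.37), p53 targets (0.25) and secreted inflammatory factors (0.92). Lower were the lists of Hox genes (-0.26), acetyl-CoA supply (-0.12), bone markers (-0.49), matrix (-0.091), fatty acid synthesis (-0.47), fibroblast identity (-0.52) and sterol synthesis (-1.08). With an estimated correlation, ER folding and sterol synthesis (camera adjusted p = 0.00742 each), bone and fatty acid synthesis (0.0464 each), and p53 and secreted factors (0.033 each) passed. The acetyl-CoA call of camera at its preset correlation was lost with the replicate number as a term (adjusted p = 0.0625), with length trends removed (0.0788) and without the libraries numbered 4 (0.0535). Length trends also ended those of matrix (0.121) and early response (0.061).

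For Cyto against KO, ATF4 targets (1.00), ER folding (2.23), NRF2 targets (0.21), early response (0.49), interferon response (0.99) and p53 targets (0.32) were higher in 1 mM glucose. Hox genes (-0.61), cell cycle (-0.39), matrix (-0.52), fibroblast identity (-0.74), glycolysis (-0.37) and sterol synthesis (-1.0) were lower. ER folding (0.0161), fibroblast identity (0.0191), interferon (0.0472) and p53 (0.0359) passed with an estimated correlation. The NRF2 call was lost without the libraries numbered 4 (0.061).

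For Nuc against KO, the higher lists were ATF4 targets (0.65), ER folding (2.18), early response (0.57), p53 targets (0.22) and secreted factors (0.59). The lower lists were Hox genes (-0.50), TGF-beta targets (-0.39), matrix (-0.47), fatty acid oxidation (-0.27), fibroblast identity (-0.70), hypoxia (-0.40) and sterol synthesis (-0.91). ER folding and fibroblast identity (0.00356 each), and hypoxia, p53 and sterol synthesis (0.0473 each), passed with an estimated correlation. The TGF-beta call was lost with the replicate number as a term (0.0669) and without the libraries numbered 4 (0.0506), and that of fatty acid oxidation without those libraries (0.0602). For Nuc against Cyto, actin and contractile genes (0.30), cell cycle (0.44) and glycolysis (0.35) were higher, and ATF4 targets (-0.19), NRF2 targets (-0.23), adipocyte markers (-0.40) and interferon response (-0.85) lower. Of these, NRF2 and actin (0.0336 each) and adipocyte and interferon (0.0284 each) passed with an estimated correlation, and the ATF4 call was lost without the libraries numbered 4 (0.118).

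Named genes also differed between media, by limma with standard errors after ±, as the log2 fold change in 1 mM minus that in 10 mM glucose. For WT against KO, Acly differed by 0.88 ± 0.11, Sdf2l1 by 3.19 ± 0.25, Creld2 by 2.79 ± 0.22, Hyou1 by 1.98 ± 0.11, Etv5 by 1.40 ± 0.12 and Abca1 by 1.29 ± 0.24. Below 0 were Clu (-2.34 ± 0.16), Txnip (-2.34 ± 0.26), Acss2 (-2.09 ± 0.20), Prelp (-2.04 ± 0.16), Acat2 (-1.75 ± 0.16), Nsdhl (-1.66 ± 0.14), Idi1 (-1.41 ± 0.12), Sc5d (-0.88 ± 0.14), Acsl3 (-0.46 ± 0.11) and Fbln5 (-0.31 ± 0.07).

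For Cyto against KO, the differences were 1.29 ± 0.12 for Acly, 4.90 ± 0.26 for Sdf2l1, 4.06 ± 0.23 for Creld2, 3.34 ± 0.11 for Hyou1, 3.51 ± 0.13 for Hmox1, 3.36 ± 0.21 for Slc7a11, 2.41 ± 0.31 for Ifit1 and 1.14 ± 0.43 for Ankrd1. The sign for Ankrd1 changed with 1 added on the linear scale (-0.16, adjusted p = 0.574), and its call was lost when any 1 of 8 libraries was left out. Negative differences were those of Aspn (-2.55 ± 0.11), Cd248 (-2.54 ± 0.17), Col8a1 (-2.33 ± 0.14), Acat2 (-2.08 ± 0.17), Fasn (-1.67 ± 0.12), Uhrf1 (-0.46 ± 0.12) and Sc5d (-0.40 ± 0.14), whose call was lost when any 1 of 3 libraries was left out (adjusted p up to 0.0712).

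For Nuc against KO, Sdf2l1 (4.77 ± 0.25), Creld2 (4.19 ± 0.22), Hyou1 (3.13 ± 0.11), Etv5 (1.72 ± 0.12), Hk2 (0.59 ± 0.11) and Acly (0.38 ± 0.11) had larger values in 1 mM glucose. Smaller ones belonged to Txnip (-3.53 ± 0.26), Prelp (-2.09 ± 0.16), Clu (-1.91 ± 0.16), Acat2 (-1.74 ± 0.16), Nsdhl (-1.34 ± 0.14), Acss2 (-1.32 ± 0.20), Mmp2 (-1.03 ± 0.08), Loxl2 (-0.55 ± 0.21) and Mcm4 (-0.20 ± 0.08). For Nuc against Cyto, Anxa8 (2.34 ± 0.11), Tagln (2.09 ± 0.22), Cdc6 (1.26 ± 0.15), Aurkb (0.93 ± 0.14), Rrm2 (0.71 ± 0.12), Pltp (0.66 ± 0.10) and Fdft1 (0.62 ± 0.13) had positive differences. Hmox1 (-2.72 ± 0.13), Adamts9 (-2.17 ± 0.17), Slc1a3 (-2.11 ± 0.16), Ifit3 (-1.43 ± 0.22), Gclc (-1.03 ± 0.10), Acly (-0.91 ± 0.12) and Mmp2 (-0.55 ± 0.08) had negative ones. For Nuc against KO, single libraries also decided the calls of Loxl2 (adjusted p up to 0.103 without 1 library) and Mcm4 (up to 0.0915), and that of Acly was lost with quantile normalization (0.111). The highest adjusted p was 0.0024, 0.0332, 0.0399 and 8.94e-04 in the 4 comparisons.

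The ER folding genes were weighed as the list with the largest difference. A trend on transcript length does not account for them, since their medians against KO in 1 mM glucose were at least 1.01 times as large once each library's trend was removed. Faster growth of cells with ACLY is argued against as well, because the largest of the 3 cell cycle medians against KO in 1 mM glucose was -0.44. Glucose and sequencing batch cannot be told apart for the difference between media, since 0 batches held both media. The response to ACLY within 1 mM glucose does not cross batches, and there an effect of ACLY, a difference between the cell lines and an effect of culture stay open.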

How the results depend on the processing

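The tests with each library's length trend removed and without all libraries numbered 4 were chosen only after the result was seen. Planned but not run were Cyto replicate 3 in 10 mM glucose, which was not analysed here, and a fit of 2 groups alone for differences between media.

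All counts of genes called stayed within 1.5 times their value under every alternative run except limma's arrayWeights for the difference between media in Nuc against Cyto, which gave 3672. The cause was not tested. Without each library in turn they also did: WT against KO gave 4588 to 5140 genes in 10 mM and 6404 to 7261 in 1 mM glucose, and Nuc against Cyto 3163 to 4108 and 4331 to 4618. The replicate number as a term gave 5745 and 6859 for WT against KO, and 6259 and 7073 for Nuc against KO. Deviations of libraries with the same number had a correlation above 0.1 in 5 of 21 pairs in 10 mM glucose, namely KO with Nuc at numbers 1, 2 and 4 and WT with KO and with Nuc at number 4, and in 5 of 24 in 1 mM glucose. The correlations ran from -0.026 to 0.403 in 10 mM glucose and from -0.207 to 0.163 in 1 mM glucose.

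Genes that followed WT numbered 1393 in Cyto, 1608 in Nuc and 982 in both in 10 mM glucose by a fold of at least 1.5 whatever the p, and 2101, 2128 and 1662 in 1 mM glucose. That rule by construction drops called genes with smaller folds.

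List counts depended on the test. Camera with an estimated correlation called, for WT, Cyto and Nuc against KO and Nuc against Cyto in that order, 5, 6, 3 and 3 lists in 10 mM, 0, 0, 0 and 1 in 1 mM glucose, and 6, 4, 5 and 4 for the differences between media. For Cyto and Nuc against WT it called 0 and 0 in each medium. At an unadjusted p under 0.05 the comparisons with 0 had 4, 5 and 4 against KO in 1 mM glucose, and 6 and 2 in 10 mM and 3 and 3 in 1 mM glucose against WT. Fry, in the same order, called 19, 20, 25 and 23 in 10 mM and 18, 27, 23 and 24 in 1 mM glucose, 22 and 16 against WT in 10 mM and 25 and 15 in 1 mM glucose, and 26, 19 and 14 for the differences of Cyto and Nuc against KO and Nuc against Cyto. Fry does not compare a list with other genes. Removing length trends left camera with 0 lists for Nuc against WT in 10 mM glucose. Of 144 list calls, 37 held with an estimated correlation, 142 with fry, 144 with equal medians, 142 with the replicate term and 134 with length trends removed, and 85 of 94 held without the libraries numbered 4. No list that passed in both settings changed direction.

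Over 356 gene results and 6573 alternatives, 34 calls were lost, 2 gained and 1 called value changed sign. Ankrd1 for the difference in Cyto against KO became -0.16 (adjusted p = 0.574) with 1 added on the linear scale, which shrinks low values, and lost its call (0.0519 to 0.0953) without KO replicate 2 or any Cyto library in 10 mM glucose, without KO replicate 1, 3 or 4 or Cyto replicate 1 in 1 mM glucose, and with arrayWeights (0.0909). The Loxl2 difference in Nuc against KO lost its call (adjusted p up to 0.103) without KO replicate 1 or Nuc replicate 1, 2 or 3 in 10 mM glucose, or KO or Nuc replicate 1 or 4 in 1 mM glucose. That of Mcm4 did so (up to 0.0915) without KO replicate 2, 3 or 4 or Nuc replicate 1 or 2 in 10 mM glucose, or KO replicate 3 or 4 or Nuc replicate 1 or 4 in 1 mM glucose, with length trends removed (0.266) and without the libraries numbered 4 (0.0551). The Sc5d difference in Cyto against KO lost its call without Cyto replicate 1 or 4 in 10 mM or 2 in 1 mM glucose (up to 0.0712) and without the libraries numbered 4 (0.0603). Acly lost the call of its difference in Nuc against KO with quantile normalization (0.111). The other changes were those of Acly in Cyto against WT, where the value in 1 mM glucose, not called, changed from -0.06 to a called 0.27 with quantile normalization. The cause was not tested. The unknown depth limits statements on genes near the lowest value.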

Other observations

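The test of the Acly level for the sterol genes and the search for genes near the lowest value, were chosen only after the result was seen.

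Within each medium, other splits of the libraries of a comparison were fitted in the same way, 35 per comparison with the real 1 included. Only 1 split, the real 1, gave as many genes in each of the 12 comparisons, the fewest that 35 splits can give. Mixed splits put the difference between the groups into the spread, which favours the real split in advance. The splits therefore do not exclude chance, and they cannot tell an effect of ACLY from a difference between cell lines. In 10 mM glucose the real counts and the highest others were 5218 and 0 for WT against KO, 4927 and 2648 for Cyto against KO, 5800 and 722 for Nuc against KO, 3963 and 2154 for Nuc against Cyto, 4033 and 1054 for Cyto against WT, and 3685 and 1 for Nuc against WT. The counts in 1 mM glucose were 7014 and 15, 7802 and 1, 7232 and 1, 4939 and 1, 6418 and 80, and 4718 and 6. The high others of comparisons with Cyto in 10 mM glucose moved only replicate 4 of the larger group to the Cyto side and left the groups otherwise whole.

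Sterol genes were lower in Nuc than in Cyto in both media. Less Acly transcript in Nuc is argued against as the whole cause of this difference, while ACLY protein was not measured. Sterol medians against KO lay below 0 in every construct, though the list did not pass in Cyto in 10 mM glucose. Less Acly transcript thus predicts higher sterol genes, yet the Nuc against Cyto medians were -0.41 in each medium. Against WT, Cyto in 10 mM glucose (Acly -0.47) and Nuc in 1 mM glucose (Acly -1.60) had higher sterol genes by camera, as a level effect predicts. Fry did not call the latter (adjusted p = 0.217). Nuc in 10 mM glucose also had less Acly than WT (-1.09), but its sterol list was not called against WT, which a level effect does not predict. Cyto in 1 mM glucose also had higher sterol genes than WT, without a called difference in Acly. A part played by the level is therefore not excluded. A length trend is argued against too, because the medians were at least 1.01 times as large once it was removed. A difference in the place of ACLY stays open as a hypothesis, and so does a difference between cell lines, which was not tested because the labels name no other line of any construct.

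Some genes were near the lowest value in 1 construct and well expressed in another. A mean log2 level under 0 in a construct and of at least 4 in another was met by 12 genes in 10 mM and 19 in 1 mM glucose, of which some follow. Sgce, an imprinted gene, was at -0.79 ± 0.93 (SD, n = 4) in KO and 5.66 ± 0.08 in WT in 10 mM glucose, and at -0.73 ± 0.40 and 5.86 ± 0.14 in 1 mM glucose. Cyto had 4.12 and 2.45 and Nuc 4.27 and 3.61. Mef2c, a transcription factor gene, was at -2.45 in WT against 3.94 in KO in 10 mM glucose, and at -1.84 against 4.02 in 1 mM glucose. Cyto had 1.90 and 4.06 and Nuc 4.72 and 4.30, so the low level was that of WT and not of every ACLY construct. Naalad2 was at -2.69 and -3.17 in WT against 3.67 and 3.82 in KO, 3.89 and 4.33 in Cyto and 5.13 and 4.58 in Nuc. Pax2 was low in WT and Cyto (-0.31 and -2.48 in 10 mM glucose) with 4.58 in KO and 0.42 in Nuc, Gpm6b in Cyto and Nuc (-0.66 and -1.36) with 4.82 in KO and 3.71 in WT, and Fbn2 in Cyto (-0.37) with 5.90 in WT, 1.38 in KO and 2.27 in Nuc. In 1 mM glucose Fbn2 was low in Nuc too, at -1.73 against -0.40 in Cyto, 0.74 in KO and 6.42 in WT.

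Rhox5, a homeobox gene, was at 6.52 in KO, 0.10 in WT, 3.41 in Cyto and 0.60 in Nuc in 10 mM glucose, and at 6.32, -1.24, 6.09 and 0.66 in 1 mM glucose. Tgfbi, a matrix protein gene, was at 4.99 in KO and at 0.10, 1.46 and 1.18 in WT, Cyto and Nuc in 10 mM glucose. Its levels in 1 mM glucose were 5.66, -0.56, -1.93 and -0.82. Peg10 was at the lowest value of the table in all 4 KO libraries in 10 mM glucose, and at 1.73 in WT, -0.89 in Cyto and -0.18 in Nuc. C3 was at 5.99, 6.11, 5.07 and 1.63 in KO, WT, Cyto and Nuc in 10 mM glucose, and at 7.33, 5.87, 8.82 and 3.32 in 1 mM glucose. Whether these levels follow ACLY or the history of each cell line was not tested.

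As shares of the nominal CPM total, mitochondrially encoded transcripts were lower in WT, Cyto and Nuc than in KO libraries. Nuc in 1 mM glucose did not pass. Dividing by each library's own sum would lower them further against KO, because every KO sum was below every other sum of its medium. That test was not run, so the Nuc result in 1 mM glucose holds for the nominal total only. In 10 mM glucose the shares were 3.51% in WT, 4.07% ± 0.329 in Cyto and 4.16% ± 0.0534 in Nuc against 4.74% in KO, with an exact permutation p = 0.0286 each, the smallest it can give with 4 against 4 or 3 against 4 libraries, and an adjusted p = 0.0343 over 6 comparisons. In 1 mM glucose WT had 1.25% and Cyto 0.958% ± 0.0787 against 1.76% in KO with the same p, and Nuc had 1.51% ± 0.172 (exact permutation p = 0.0857, adjusted p = 0.0857).

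Other lists gave these values. Genes of homologous recombination and the DNA damage response were lower than in KO in 10 mM glucose, with 14, 17 and 12 of 25 down in WT, Cyto and Nuc, and 15, 19 and 15 adjusted over the list alone (medians -0.46, -0.75 and -0.40, camera adjusted p = 7.92e-04, 2.65e-06 and 0.00333). None of these held with an estimated correlation (0.225, 0.0786 and 0.28). Hox and positional genes were lower than in KO in 1 mM glucose in Cyto (18 of 28 down, also adjusted over the list alone, median -0.47, adjusted p = 0.00584) and in Nuc (18 down, also adjusted over the list alone, median -0.60, adjusted p = 0.0174), again not with an estimated correlation (0.208 and 0.345). Oxidative phosphorylation genes were lower than in WT in 1 mM glucose in Cyto (18 of 32 down, also adjusted over the list alone, median -0.25, adjusted p = 0.00203) and in Nuc (15 down, also adjusted over the list alone, median -0.25, adjusted p = 0.00284), neither with an estimated correlation (0.688 and 0.822), and fry did not call the latter (adjusted p = 0.0724). The list of lysine acetyltransferases had 5 of 18 genes down and 1 up (5 and 0 adjusted over the list alone) in Nuc against KO in 10 mM glucose and did not pass (median -0.21, adjusted p = 0.227).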
